A study of Homo sapiens with 9 samples.

How the data were processed

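Total RNA of the A673 cell line had been hybridised to 9 one-colour Affymetrix Human Genome U95 arrays (version A), 3 each of the wild-type, empty vector and IL-2 transgenic lines, with experiments numbered 1 to 3 in each group, per the labels. The deposited table held 1 linear intensity per probe set and array, never negative. Software, background correction and detection calls were not given in the sources used here. The values showed a scaling by array, since the 2% trimmed means of the 9 deposited columns lay between 500.2 and 500.3. No probe set's alignment to the genome was given, so probe sets were named by gene symbol.

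The table of 12626 probe sets held 67 control probe sets, which were left out of all tests. Of the others, 10943 had 1 gene symbol in the platform's annotation, 546 had several and 1070 had none. Symbols were checked against a RefSeq gene table of the assembly GRCh38.p14 through gene identifiers, which matched 10934 probe sets and changed 0 symbols. No gene was named from a probe set with several symbols. Probe sets whose identifiers end in _s_at, _f_at, _g_at, _i_at or _r_at are ones that the array's design marks as open to cross-hybridisation or as chosen under relaxed rules. Of columns without a sample in the labels there were 0.

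The design, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Because the trimmed means lay within 10% of each other, no further normalization was applied. The pseudocount was the 25th percentile of the table (55.9) rounded to 60, and tests used log2(intensity + 60). A probe set was tested when at least 3 of the 9 arrays lay above the median of the table (186.8), which left 7032 probe sets, 6229 of them with 1 gene symbol, for 5182 genes. All 9 arrays entered 1 linear model with a coefficient per group and 6 residual degrees of freedom (limma 3.58.1 with statmod 1.5.0, R 4.3.3, lmFit and eBayes with an intensity trend). The 3 comparisons of groups were contrasts of this model, tested two-sided with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. A count of probe sets past the threshold in the same direction against both control lines was set beside 100 simulations of groups without effects on the same arrays. IL2, whose probe sets lay below the filter, was tested without the filter and by an exact permutation test on log2 values.

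The genes named in the text were IL2, the 10 genes with the largest change in each direction of each comparison, the 5 in each direction with the largest smaller change in both IL-2 comparisons, up to 4 members past the threshold of each fixed list, and 9 genes fixed by name. The first of these had to pass the threshold with groups that did not overlap, 1 gene symbol and a higher group mean above the median of the table, and the probe set with the largest passing change stood for the gene. Members of the lists that did not pass, and runs of neighbours, were named after their values had been seen. The 25 lists covered IL-2 signalling, interferon-stimulated genes, MHC class I and II, ligands of natural killer and T cells, cytokines, NF-kappaB targets, genes activated or repressed by EWS-FLI1, cancer-testis antigens, cell cycle, immediate early genes, hypoxia, unfolded protein stress, heat shock, cholesterol, oxidative stress, extracellular matrix, neural genes, apoptosis, ribosomal proteins, and markers of lymphocytes, myeloid cells, fibroblasts and epithelium. Each gene entered by its brightest tested probe set, and limma's camera was run with a preset correlation of 0.01, with adjustment over the 25 lists of a comparison.

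Arrays with the same experiment number were checked for pairing by the correlation of their deviations from the group means across probe sets. The correlations were 0.228 to 0.394 for the IL-2 and empty vector lines and 0.141 to 0.250 for the IL-2 and wild-type lines, and 0.0940 to 0.251 for the empty vector and wild-type lines. Where all 3 exceeded 0.1 the numbers were taken to pair the arrays, which held for the 2 comparisons of the IL-2 line. In the third comparison too, each empty vector array correlated most with the wild-type array of its own number. Blocked values were given beside the counts of probe sets and the list calls that the block ended. They were not given for every count of list members that the block changed. The pairing came from experiment numbers in the labels, which name no shared day or batch. An Alu control probe set read 61698 to 69989 on the 3 arrays of experiment 1 and 17497 to 31484 on the others. The 3'/5' ratios of the GAPDH controls lay between 0.727 and 1.19 and those of the ACTB controls between 0.972 and 1.49.

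The steps were tested on simulated arrays with the probe sets' means and residual spreads in the deposited table. With 200 of 7032 probe sets changed, the model recovered 77.1%, 75.5% and 75.1% of 4-fold changes, 24.9%, 23.5% and 21.1% of 2-fold changes and 2.54%, 1.72% and 1.72% of 1.5-fold changes in the IL-2 and empty vector, IL-2 and wild-type, and empty vector and wild-type comparisons, with 4.22%, 4.44% and 3.93% false calls. Camera found 20 of 20 shifted lists and called 2 of 480 unshifted ones, and the search for runs found all 5 planted runs and 0 others. The simulated genes varied independently, whereas members of many real lists moved together (estimated correlation up to 0.803, ribosomal proteins). These rates of false calls therefore do not carry over to the real lists or runs. The estimated correlation lay below the preset 0.01 for the interferon-stimulated genes (-0.0012), the ligands (-0.0333) and the lymphocyte markers (-0.0675). For these lists a higher adjusted p with an estimated correlation does not show that members moved together. Runs were found from the median log2 difference of 21 neighbouring genes, tested against 999 shuffled gene orders with the family-wise threshold at 0.05, over 4981 genes with a known place on chromosomes 1 to 22.

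The alternatives were quantile normalization, median centring, a pseudocount of 15 or 240, no filter or one at the 75th percentile, eBayes without the trend, only the 2 groups compared, array weights, the experiment number as a block, and leaving out each array or each experiment number. For the lists they were an estimated correlation, fry, the mean over the probe sets of a gene, quantile normalization, median centring, no filter and the block. Leaving out arrays from the list tests, and all tests on runs of neighbours, were added after the data had been seen. HLA-B and NR0B1 were not analysed here, because no probe set was named for either alone.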

Results

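RNA of the human Ewing family tumour cell line A673 was measured on 9 one-colour oligonucleotide arrays of 12626 probe sets. The labels gave 3 groups of 3 arrays each, namely the unmodified (wild-type) line, a line that had received an empty vector, and a line described as IL-2 transgenic, here called the IL-2 line. Each group held experiments numbered 1, 2 and 3. The values were intensities without detection calls, and every array had been brought to the same trimmed mean, between 500.2 and 500.3. The median intensity of an array lay between 159 and 205.9. Pairs of arrays of the same group correlated at r = 0.887 to 0.943 over the probe sets tested, and pairs of different groups at 0.856 to 0.946. The number of arrays limited the precision of each comparison. Nothing in the labels said that the replicates were separate cultures, so the p-values measured the spread between these arrays, which may be technical, and with 1 line per construct they did not cover differences between independently made lines. Fold changes were taken on the scale of log2(intensity + 60), which understates changes of dim genes, and folds against a dim group move with the constant added (PEG3 in the IL-2 and empty vector lines from log2 6.40 to 4.18).

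IL2, the gene of the T-cell growth factor that the IL-2 line was made to carry, was read by 3 probe sets, and none of them rose above background on any array. Their intensities lay between 3.4 and 76.2 on all 9 arrays, and at most 32.6% of an array's probe sets were dimmer. The brightest of them gave 52.6 ± 38.9 (SD, n = 3) in the IL-2 line, 32.2 ± 18.2 in the empty vector line and 8.57 ± 2.51 in the wild-type line. On the 3 IL-2 arrays it read 7.7, 74 and 76.2. The log2 difference of the IL-2 line was 0.24 from the empty vector line (exact permutation p = 0.6, two-sided) and 0.65 from the wild-type line (exact permutation p = 0.3), where 3 arrays against 3 cannot give a p below 0.1. Without experiment 1 of the IL-2 line these differences were 0.57 and 0.98. The arrays therefore gave no check of which line carried the gene, and whether the probe sets could read the transgene was not known.

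The comparison of the IL-2 line with the empty vector line asked which transcripts differ between 2 transfected lines, of which 1 was given IL-2. The imprinted zinc finger gene PEG3 stood at 5292 ± 1687 (SD, n = 3) in the IL-2 line and at 58.9 ± 53.8 in the empty vector line, a 46.6-fold difference (log2 5.54 ± 0.56 SE, limma adjusted p = 0.000228). The neuronal transcription factor POU4F1 was 12.1-fold higher (3798 ± 2080.0 against 231 ± 95.6), and the tetraspanin TSPAN8 differed by log2 3.91 (2716 ± 2833 against 99.4 ± 129, with 5964, 1434 and 751 on the 3 IL-2 arrays). MICB, a stress-induced ligand of natural killer cells, was 9.54-fold higher (1212 ± 474 against 68.8 ± 25.3, adjusted p = 0.000429). The actin-capping protein gene CAPG and CYBA, a subunit of the NADPH oxidase, were 9.47-fold and 9.44-fold higher. CAT, which encodes catalase, fell 9.42-fold to 16.0 ± 0.862 from 670.3 ± 171 (log2 -3.24 ± 0.28 SE, adjusted p = 0.000124), where 16.0 is a background level and the size depends on the pseudocount (log2 -4.43 with 15 and -1.81 with 240). The platelet-derived growth factor receptor gene PDGFRB was lower by both of its probe sets (log2 -2.37 and -1.45). In all, 111 of 7032 probe sets passed an adjusted p of 0.05, of which 65 were higher and 46 lower in the IL-2 line, and 101 of them changed at least 2-fold. They held 57 named genes that were higher and 38 that were lower. With the experiment number as a block the count was 235, with 127 higher and 108 lower. The 2 groups did not overlap at 16.5% of the probe sets tested, where chance gives 10%.

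Further named genes that were higher in the IL-2 line than in the empty vector line were ALDH2, the mitochondrial aldehyde dehydrogenase (log2 2.86), ARMCX2 (2.65), the sugar phosphate enzyme gene PGM1 (2.56), the sodium pump subunit ATP1B1 (2.52) and the virus receptor and adhesion gene CXADR (1.39). The lower ones were EMILIN1 (-2.33), the elongation factor gene EEF1A2 (-2.32), the slow muscle troponin gene TNNT1 (-2.13), the lymphotoxin beta receptor LTBR (-2.07), the collagen processing factor PCOLCE (-1.79), LMO2 (-1.66), the respiratory complex III gene CYC1 (-1.54), the GTPase RHOB (-1.53) and the nuclear lamin gene LMNB1 (-1.42). Their adjusted p lay between 0.00292 (PGM1) and 0.0451 (RHOB). ARMCX2 stood at 17.5 ± 7.57 (SD, n = 3) in the empty vector line, and EMILIN1 and LTBR at 41.8 ± 14.9 and 49.5 ± 16.3 in the IL-2 line. These are background levels, so the sizes of these 3 differences depend on the pseudocount. The probe sets of a gene disagreed for EEF1A2, whose other probe set gave 0.07, and differed in call for TNNT1, whose other probe set gave -0.86. POU4F1, PGM1, CAT, PDGFRB, LMO2 and CYC1 lay in runs of chromosomal neighbours that were shifted the same way, whereas PEG3, TSPAN8, MICB, CAPG and CYBA did not. A run spans all genes of its windows, so the nearest neighbours of a member may shift less. The nearest neighbours, up to 20, had median log2 differences of -0.76 (CAT and LMO2) and -0.72 (CYC1). Those of POU4F1, PGM1 and PDGFRB had 0.34, 0.26 and -0.23. LMNB1 lay in a lower run and was also the last gene of a higher one (CETN3 to LMNB1, median 0.30). Of 33 named calls in this comparison, 17 held without any 1 of the 9 arrays, among them PEG3, POU4F1, MICB, CAPG, CYBA, CAT and PDGFRB. The count of 111 fell to 50 and 59 without experiment 2 or 3 of the empty vector line, and to 67, 64 and 63 without experiment 1, 2 or 3 of the IL-2 line.

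**Figure D1:**
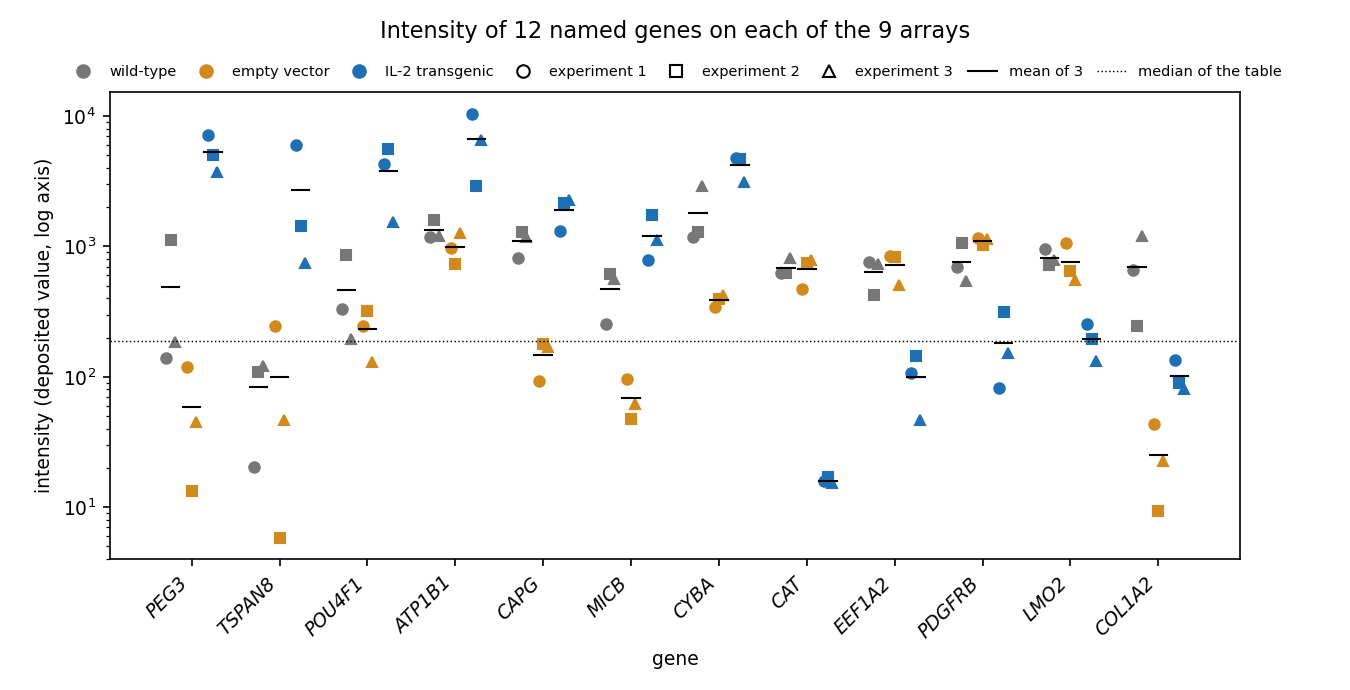
Deposited intensity (log axis) of 12 named genes on each of the 9 arrays, with colour for the line, shape for the experiment number, a short bar for the mean of 3 arrays and a dotted line at the median of all values of the table (186.8). PEG3 reads 3739 to 7087 on the 3 IL-2 arrays and 13.2 to 118.2 on the 3 empty vector arrays, and CAT reads 16.0 on average in the IL-2 line against 670.3 and 688 in the empty vector and wild-type lines.

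Among the gene lists, 15 of the 16 heat shock genes measured were lower in the IL-2 line than in the empty vector line, with a median log2 difference of -0.27. This list passed limma's camera test with a preset correlation of 0.01 (adjusted p = 0.000179), while the adjusted p was 0.347 with an estimated correlation. Against the wild-type line 9 of the 16 were higher, with a median of 0.02 (adjusted p = 0.283). The small chaperone HSPB1 (6950.0 ± 1524 against 17904 ± 812, SD, n = 3) and the mitochondrial chaperone HSPA9 (671 ± 97.9 against 1653 ± 97.4) fell past the threshold over all probe sets, and 4 members were called lower adjusted over the list alone. Of 11 genes of MHC class I antigen presentation, 9 were lower, with a median of -0.50 (adjusted p = 0.00693, and adjusted p = 0.347 with an estimated correlation). HLA-F (an _f_at probe set, 498 ± 122 against 1078 ± 238) was the member called over all probe sets, 2 were called adjusted over the list alone, and related HLA genes share sequence that this probe set may read. Of 21 type I interferon-stimulated genes, 13 were lower, with a median of -0.16 and no member called (adjusted p = 0.0333, and adjusted p = 0.347 with an estimated correlation). With the experiment number as a block 1 member was called lower. Against the wild-type line the median of this list was -0.09 (adjusted p = 0.649). Of 45 ribosomal protein genes, 41 were lower, with a median of -0.24 (adjusted p = 0.000217, and adjusted p = 0.966 with an estimated correlation). RPL30 (log2 -1.02) was the member called, and 1 higher and 3 lower members were called adjusted over the list alone. Of 10 ligands of natural killer and T cells, 8 were higher, with a median of 0.38 (adjusted p = 0.0468, and adjusted p = 0.347 with an estimated correlation), and MICB was the member called, also adjusted over the list alone. Limma's fry gave the ligands an adjusted p of 0.0458. With the experiment number as a block the camera adjusted p of the ligands was 0.0723, after quantile normalization 0.0772, and without the filter on dim probe sets 0.597. Without single arrays it was 0.0526 and 0.0536 (wild-type 2 and 3), 0.0612, 0.0732 and 0.0522 (empty vector 1, 2 and 3), and 0.135 and 0.171 (IL-2 experiment 2 and 3). Without empty vector experiment 1 the adjusted p was 0.634 for the ribosomal genes, 0.0939 for MHC class I and 0.0612 for the interferon-stimulated genes, which also had 0.0732 without empty vector experiment 2 and 0.171 without IL-2 experiment 3, and 0.0629 with the mean over all probe sets of a gene. The ribosomal genes had 0.0571 without IL-2 experiment 2 and 0.344 after quantile normalization. The ribosomal median was 0.00 (mean -0.04) without empty vector experiment 1, -0.40 without empty vector experiment 3, and -0.42 and -0.11 without IL-2 experiment 1 or 2. The median of the interferon-stimulated genes was -0.39 without empty vector experiment 1 and -0.28 without IL-2 experiment 1, and that of the ligands 0.25 without IL-2 experiment 3. Of the members named here, the calls of HSPA9 and MICB held without any 1 of the 9 arrays. Those of HSPB1, HLA-F and RPL30 did not.

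Single members of further lists passed the threshold while their lists did not. CD99, a surface protein used as a marker of Ewing tumours and listed here among genes activated by the EWS-FLI1 fusion, was 2.12-fold higher in the IL-2 line (21751 ± 4379, SD, n = 3) than in the empty vector line (10252 ± 2175). The wild-type line read 19042 ± 662. The empty vector line differed from it by log2 -0.91 (limma adjusted p = 0.269, and 0.0361 with the experiment number as a block). TNNT1, on the same list as CD99, was lower in the IL-2 line than in the empty vector line by 1 of its 2 probe sets (log2 -2.13). The other gave -0.86 and did not pass. LGALS1, listed among genes repressed by EWS-FLI1, was 2.52-fold lower (5776 ± 1948 against 14348 ± 3526). The collagen IV genes COL4A1 (log2 1.74) and COL4A2 (1.42), the endoplasmic reticulum chaperone gene HYOU1 (1.14) and TM7SF2, a sterol reductase gene (1.56), were higher. All 4 lay in runs of chromosomal neighbours that were also higher. Of the calls of these single members, only that of COL4A2 held without any 1 of the 9 arrays. Of the 32 genes measured on the list activated by EWS-FLI1, 18 were higher and 14 lower in the IL-2 line than in the empty vector line (camera adjusted p = 0.564), and of the 31 on the list repressed by it, 14 were higher and 17 lower (adjusted p = 0.422).

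**Figure D2:**
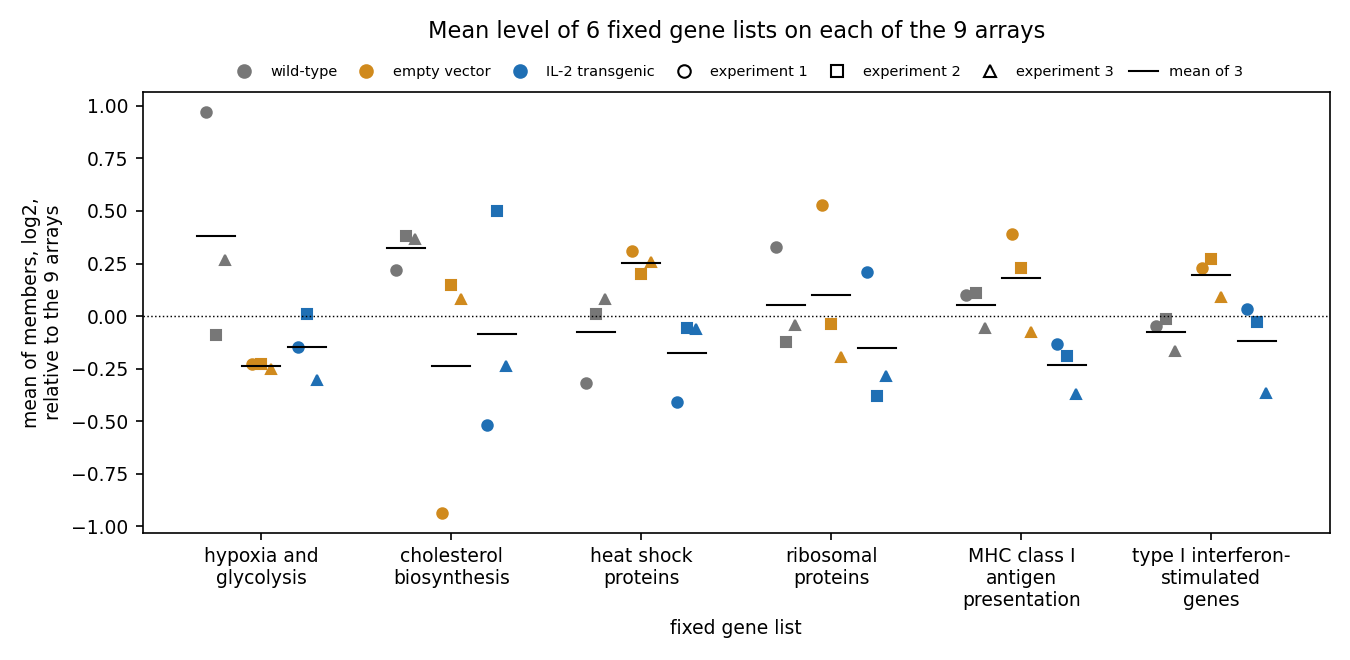
Mean log2 level of the members of 6 fixed gene lists on each of the 9 arrays, relative to the mean over all arrays, with colour for the line, shape for the experiment number and a short bar for the mean of 3 arrays. The hypoxia and glycolysis genes read 0.97 on wild-type experiment 1, -0.09 and 0.27 on the other wild-type arrays, and -0.23, -0.23 and -0.25 on the empty vector arrays.

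The comparison of the IL-2 line with the wild-type line held the transgene, the transfection and differences between lines together. TSPAN8 (2716 ± 2833 against 82.9 ± 54.4, SD, n = 3) was 14.4-fold higher in the IL-2 line (adjusted p = 0.039, and 0.0767 with a pseudocount of 15), PEG3 13.4-fold (5292 ± 1687 against 484 ± 558) and POU4F1 7.52-fold (3798 ± 2080.0 against 461.3 ± 350.8). ATP1B1 (log2 2.09) and CXADR (1.61) were the other named genes that were higher. CAT fell 9.77-fold to 16.0 ± 0.862 from 688 ± 114 (log2 -3.29 ± 0.28 SE, limma adjusted p = 0.00019). The glycogen primer gene GYG2 (log2 -2.33, from -3.58 with a pseudocount of 15 to -1.10 with 240), EEF1A2 (-2.15), PDGFRB (-1.83), LMO2 (-1.81), the actin-binding thymosin gene TMSB4X (-1.71), LMNB1 (-1.50), the triglyceride synthesis gene DGAT1 (-1.46), C5orf15 (-1.34), the respiratory complex III gene UQCRB (-1.33) and HSPA9 (-1.02) were lower. For these genes other than CAT the adjusted p lay between 0.0195 and 0.04, and the second probe sets of EEF1A2 (-0.22) and PDGFRB (-0.48) did not pass. In all, 24 probe sets passed, 8 higher and 16 lower in the IL-2 line, and 23 of them changed at least 2-fold. With the experiment number as a block 53 passed, 16 higher and 37 lower, and the groups did not overlap at 11.3% of the probe sets tested, where chance gives 10%. CAT, LMO2, LMNB1, DGAT1, C5orf15, UQCRB and HSPA9 lay in runs of neighbours that were lower, though the 20 nearest neighbours of LMNB1 had a median of -0.11. Of 16 named calls only CAT held without any 1 of the 9 arrays, and the count of 24 was 1, 6 and 4 without wild-type experiment 1, 2 or 3, 5, 8 and 9 without IL-2 experiment 1, 2 or 3, 14 without empty vector experiment 2, and 5 without the intensity trend in limma.

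Genes of hypoxia and glycolysis were lower in the IL-2 line than in the wild-type line for 30 of 33 members, with a median log2 difference of -0.38 (camera adjusted p = 8.3e-07, and adjusted p = 0.649 with an estimated correlation). No member passed over all probe sets and 1 was called lower adjusted over the list alone. The largest member values, none past the threshold, were those of GAPDH (-2.18, by a probe set at 23675 ± 28046 in the IL-2 line and 38382 ± 28568 in the wild-type line, SD, n = 3), P4HA2 (-1.70) and NDRG1 (-1.45). Without wild-type experiment 1 the median of the list was -0.16, and in experiment 2 the mean of its members was 0.10 higher in the IL-2 line. Of 24 cholesterol biosynthesis genes, 22 were lower, with a median of -0.43 and none called (adjusted p = 0.000727, and adjusted p = 0.649 with an estimated correlation), and in experiment 2 their mean was 0.12 higher in the IL-2 line. The ribosomal protein genes were lower for 39 of 45 members, with a median of -0.18 (adjusted p = 0.000727, and adjusted p = 0.743 with an estimated correlation). The list of oxidative stress genes and metallothioneins, which holds CAT, was lower for 18 of 22 members, with a median of -0.12 (adjusted p = 0.023, and adjusted p = 0.649 with an estimated correlation). The MHC class I list (8 of 11 lower, median -0.24, adjusted p = 0.0311) and the cell cycle list (32 of 48 lower, median -0.14, adjusted p = 0.0342) had an adjusted p = 0.649 and an adjusted p = 0.743 with an estimated correlation. The ligands of natural killer and T cells (8 of 10 higher, median 0.29, adjusted p = 0.0301) and the lymphocyte markers (8 of 9 higher, median 0.29, adjusted p = 0.0481, no member called) both had an adjusted p = 0.567 with an estimated correlation. With the experiment number as a block the adjusted p of the lymphocyte markers was 0.0728. Without the filter it was 0.443 for them and 0.388 for the ligands, and with the mean over all probe sets of a gene 0.0565 for MHC class I. Without IL-2 experiment 1 the adjusted p was 0.198 for cholesterol biosynthesis and 0.642 for oxidative stress (0.0503 without wild-type experiment 3), and the cell cycle genes pointed up (0.936), with 0.493 and 0.248 without wild-type experiment 2 or 3. The ribosomal genes had 0.247 without wild-type experiment 1, and 0.163 and 0.0688 without IL-2 experiment 2 or 3. MHC class I had 0.0577 and 0.200 without wild-type experiment 1 or 2 and 0.137 without IL-2 experiment 3, and the ligands 0.0675 without wild-type experiment 1 and 0.142 and 0.132 without IL-2 experiment 2 or 3. The lymphocyte markers passed without IL-2 experiment 1 and had 0.0546 to 0.215 without any other 1 of the 9 arrays. The median of the cholesterol genes was -0.20 and -0.69 without IL-2 experiment 1 or 2, and that of the cell cycle genes 0.02 and -0.34 without IL-2 experiment 1 or 3 and -0.28 without wild-type experiment 1. The ribosomal median was 0.01 and -0.28 without wild-type experiment 1 or 2 and -0.37, -0.05 and -0.10 without IL-2 experiment 1, 2 or 3, and the oxidative stress median -0.22 and -0.08 without wild-type experiment 1 or 3 and -0.02 and -0.29 without IL-2 experiment 1 or 3. The MHC class I median was -0.41 and -0.51 without wild-type experiment 1 or 3, and without IL-2 experiment 1 the ligands had 0.45 and the lymphocyte markers 0.48. After quantile normalization the calls of hypoxia and of cholesterol biosynthesis were the 2 that passed.

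The comparison of the empty vector line with the wild-type line had no transgene, so it held transfection and differences between lines. COL1A2, a chain of collagen I, was lower in the empty vector line (25.2 ± 17.1, SD, n = 3) than in the wild-type line (699.7 ± 477), where 25.2 is a background level and the size depends on the pseudocount (log2 -2.95 ± 0.49 SE with 60, limma adjusted p = 0.0421, -3.98 with 15 and -1.69 with 240, where the call was lost). CAPG was 5.61-fold lower (147 ± 47.2 against 1099.9 ± 248, adjusted p = 0.00516), MICB 3.98-fold (68.8 ± 25.3 against 474 ± 193) and CYBA 3.85-fold (385 ± 41.3 against 1792 ± 958). The cell cycle transcription factor partner TFDP1 (log2 -2.24), the kinase CAMK1 (-2.03), the chemokine receptor CXCR3 (-1.60), the helicase DDX10 (-1.51), the membrane-cytoskeleton linker RDX (-1.46) and COL4A2 (-1.18) were also lower. The second probe set of TFDP1 gave -0.86 and did not pass, while that of RDX gave -1.40 and passed. In all, limma passed 13 probe sets (437 at an unadjusted p under 0.05), 0 higher and 13 lower by at least 2-fold, and the groups did not overlap at 11.7% of the probe sets tested, where chance gives 10%. With the experiment number as a block 31 passed, 4 higher and 27 lower. TFDP1, DDX10, RDX and COL4A2 lay in runs of neighbours that were lower, though the 20 nearest neighbours of DDX10 and of RDX had a median of -0.28. None of the 10 named calls held without each 1 of the arrays, and the count was at most 2 without any 1 array other than IL-2 experiment 1 (12). It was 6 after quantile normalization, 4 after median centring, 1 with a pseudocount of 240 and 1 when the fit held these 6 arrays alone.

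Against the wild-type line, the empty vector line too had lower levels of hypoxia and glycolysis genes, in 32 of 33 members with a median log2 difference of -0.51 (camera adjusted p = 2.0e-09, and adjusted p = 0.399 with an estimated correlation). No member passed over all probe sets and 2 were called lower adjusted over the list alone. The neuronal enolase gene ENO2 read 541 ± 197 against 2408 ± 1415 (SD, n = 3), and BNIP3 461 ± 102 against 1716 ± 1389, with experiment 1 the highest wild-type array for the list. Without that array the median of the list was -0.24, and without wild-type experiment 2 it was -0.82. All 24 cholesterol biosynthesis genes measured were lower, with a median of -0.51 that was -0.20 without empty vector experiment 1, none called over all probe sets and 2 adjusted over the list alone (adjusted p = 3.2e-07, and adjusted p = 0.683 with an estimated correlation). Of 16 heat shock genes, 14 were higher, with a median of 0.30 and none called (adjusted p = 0.000145, and adjusted p = 0.399 with an estimated correlation). Of 21 interferon-stimulated genes, 15 were higher, with a median of 0.30 and none called (adjusted p = 0.0328, and adjusted p = 0.376 with an estimated correlation). All 9 lymphocyte markers measured were higher, with a median of 0.28 and none called (camera adjusted p = 0.0328, 0.0684 with the experiment number as a block, and 0.376 with an estimated correlation). Without empty vector experiment 1 the adjusted p was 0.0864 for cholesterol biosynthesis, 0.0819 for the interferon-stimulated genes and 0.0966 for the lymphocyte markers, and without empty vector experiment 2 it was 0.129 and 0.0664 for the last pair. Without wild-type experiment 2 it was 0.0561 and 0.115, and without wild-type experiment 3 it was 0.0856 and 0.0632, for that pair. Without the filter it was 0.133 and 0.452, and with the mean over all probe sets of a gene 0.0652 for the interferon-stimulated genes. Their median was 0.14 without empty vector experiment 2, and that of the lymphocyte markers 0.43 without wild-type experiment 1. With an estimated correlation camera passed 0 lists in each of the 3 comparisons, and limma's fry passed 1, 0 and 0. The list that fry passed was the ligands of natural killer and T cells, in the IL-2 and empty vector comparison.

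In the same direction against both other lines, 22 probe sets passed, 8 higher and 14 lower in the IL-2 line (47 with the experiment number as a block, 14 higher and 33 lower). TSPAN8, PEG3, POU4F1, ATP1B1 and CXADR were the named genes that were higher, and CAT, EEF1A2, PDGFRB, LMO2 and LMNB1 those that were lower. Both comparisons used the same IL-2 arrays. Simulated groups without effects gave an overlap of 0, which was nearly fixed in advance, since few probe sets can pass there at all. Independent lists of these sizes would share 0.179, but these lists are not independent. Neither value tells how many of the 22 the shared arrays brought. The log2 differences of the 2 comparisons correlated across probe sets at r = 0.615 against a simulated 0.498, with a covariance of 0.122 against 0.0676, and part of the overlap may come from the shared arrays. Of the 111 probe sets called against the empty vector line, 12 were called in the opposite direction between the empty vector and wild-type lines, among them those of CAPG, MICB, CYBA and COL4A2. These 2 comparisons share the empty vector arrays, which alone brings opposite signs (r = -0.562 against a simulated -0.501), and 77 of the 111 were called in neither of the other comparisons. The count of 22 was 1, 6 and 4 without wild-type experiment 1, 2 or 3, 10 and 14 without empty vector experiment 2 or 3, and 4, 7 and 9 without IL-2 experiment 1, 2 or 3.

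Of the genes fixed for the 2 IL-2 comparisons, the receptor chains IL2RA (21.6 ± 17.0 in the IL-2 line, SD, n = 3) and IL2RB (146 ± 37.8) stayed below the filter on intensity, and IL2RG (190.1 ± 145 in the IL-2 line, 304 ± 219.8 in the empty vector line and 170.4 ± 96.8 in the wild-type line) did not pass. The MHC class I light chain B2M did not pass by any of its 3 probe sets, which gave log2 differences of -0.25 to 0.42 from the empty vector line. The Ewing tumour transcription factor NKX2-2 gave 0.65 and 0.82 by its 2 probe sets, neither of which passed. CD99 gave 0.17 against the wild-type line, which did not pass. HLA-B and NR0B1 were not analysed here, since no probe set was named for either alone. None of the 11 measured genes of IL-2 receptor and signalling passed in any comparison.

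The other 15 lists passed in no comparison, with a camera adjusted p of 0.209 or more. In the IL-2 line against the empty vector line the adjusted p was 0.266 for neural genes (15 of 19 higher, median log2 0.28) and 0.298 for cancer-testis antigens (4 of 5 lower, median -0.39). It was 0.422 for extracellular matrix and adhesion (20 of 32 higher, median 0.14) and for immediate early genes (13 of 24 lower), and 0.756 for cytokines and chemokines (11 of 18 higher). It was 0.954 for IL-2 receptor and signalling, MHC class II, NF-kappaB targets, unfolded protein and amino acid stress, apoptosis regulators, and myeloid, fibroblast and epithelial markers. In this comparison the median, mean and test differed in sign for IL-2 receptor and signalling, NF-kappaB targets, unfolded protein stress and fibroblast markers.

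The chromosomal order of the genes, examined after the calls had been seen, showed runs of neighbouring genes that were shifted together. Over 4981 tested genes, 11 runs differed between the IL-2 and empty vector lines, 6 between the IL-2 and wild-type lines and 3 between the empty vector and wild-type lines, each at a family-wise permutation p of 0.05 or less for windows of 21 genes. On chromosome 11, 57 genes from ABCC8 to LPXN, CAT and LMO2 among them, had a median log2 difference of -0.56 from the empty vector line and -0.41 from the wild-type line. On the same chromosome 69 genes from SRSF8 to GLB1L2, HYOU1 among them, were higher in the IL-2 line than in the empty vector line by 0.65 in the median, and this stretch was lower in the empty vector line than in the wild-type line by -0.49. On chromosome 13, 30 genes from PIBF1 to CDC16, POU4F1, COL4A1 and COL4A2 among them, differed by 0.67 from the empty vector line and 0.12 from the wild-type line. On chromosome 5, 50 genes from ATG12 to DIAPH1, HSPA9 and LMNB1 among them, differed by -0.57 and -0.44. On chromosome 8, 83 genes from LY96 to ZNF250, CYC1 and RPL30 among them, differed by -0.51 and -0.38. On chromosome 1, 88 genes from TMEM59 to ITGA10, PGM1 among them, differed by 0.45 and 0.36. Neighbours were ordered by the GRCh38.p14 assembly.

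**Figure D3:**
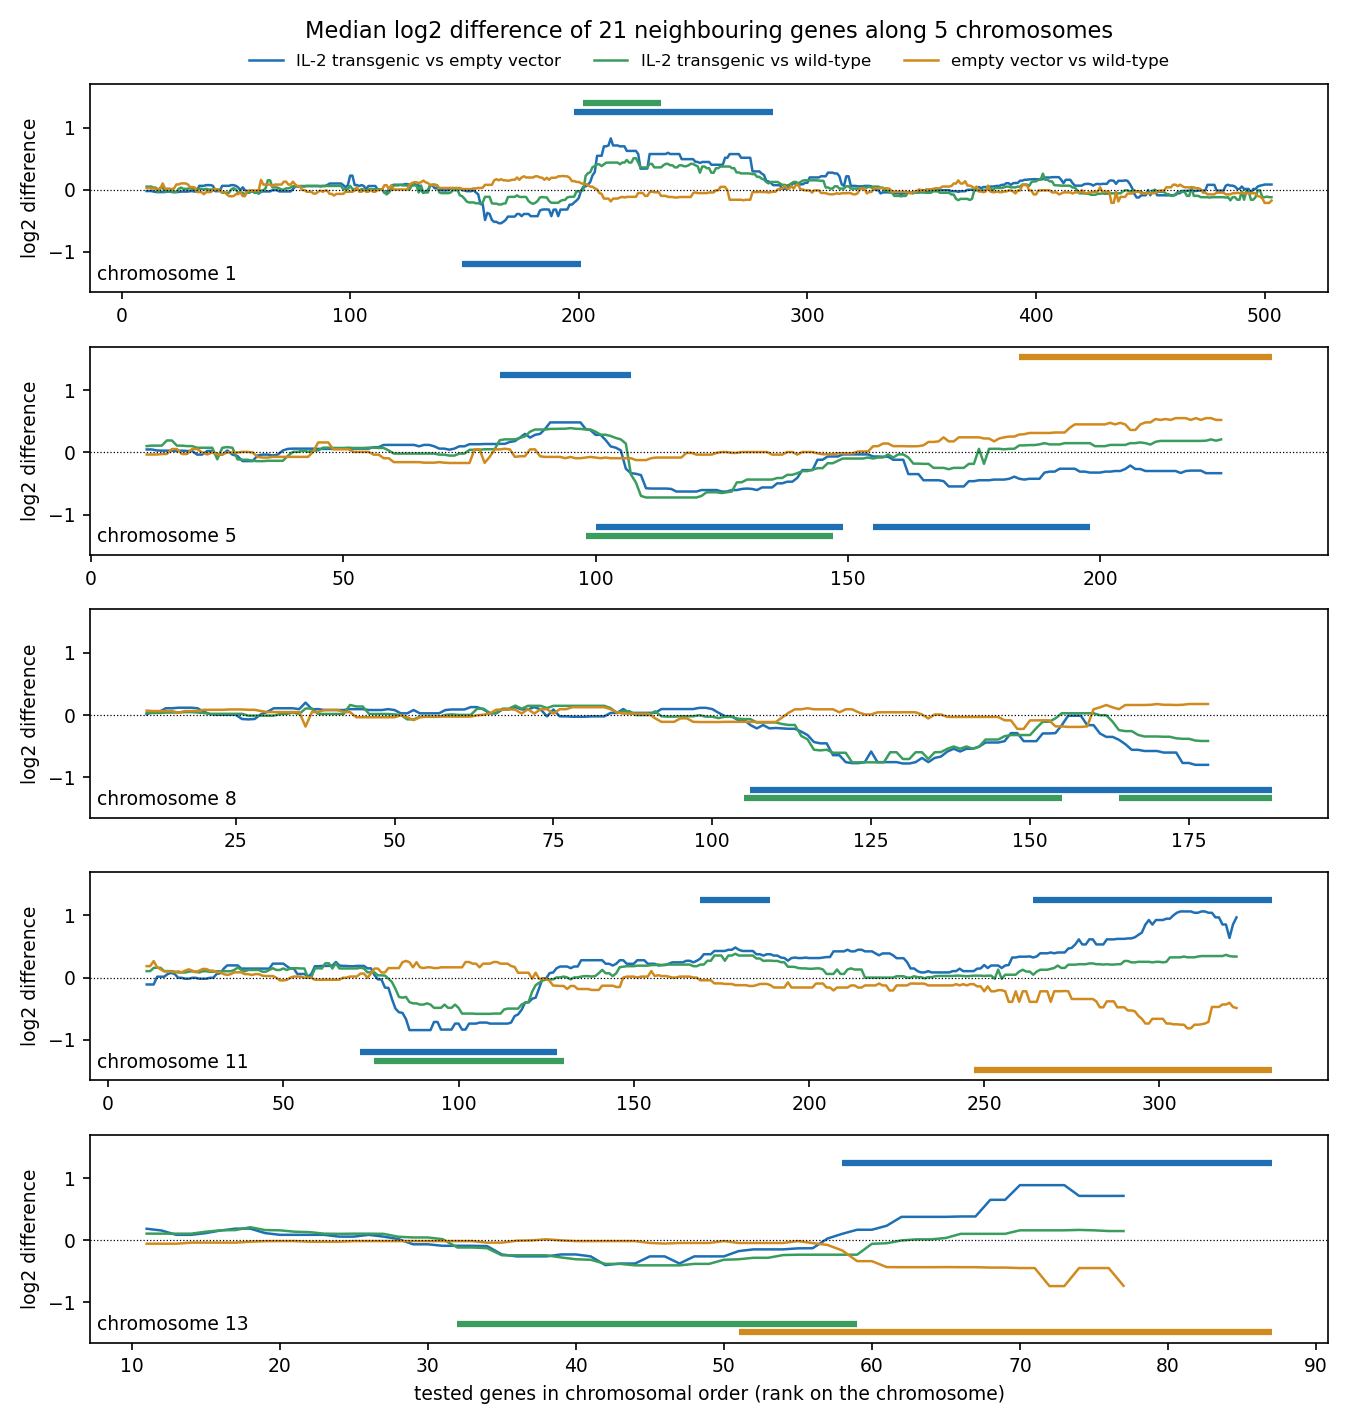
Median log2 difference of 21 neighbouring tested genes along 5 chromosomes, by rank of the gene on its chromosome, with a line for each of the 3 comparisons and horizontal bars for the runs past the family-wise threshold (bars at the top for higher runs, at the bottom for lower ones). On chromosome 11 the highest window of the IL-2 line against the empty vector line reaches 1.06, and the lowest -0.84.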

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

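Leaving out arrays from the gene list tests was chosen after the list results had been seen, and the other alternatives before them. Where a result moved with a setting, the cause was not tested.

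Quantile normalization lowered the count of probe sets in empty vector against wild-type from 13 to 6, and the lists from 5 to 3 in IL-2 against empty vector and from 8 to 2 in IL-2 against wild-type. Median centring gave 14 of 24 probe sets in IL-2 against wild-type (6 higher and 8 lower, where 8 and 16 were reported), 4 in empty vector against wild-type and 11 against both controls (22 reported). A pseudocount of 240 gave 1 probe set in empty vector against wild-type and an IL2 difference of 0.23 between the IL-2 and wild-type lines, and one of 15 gave IL2 differences of 1.28 (IL-2 against wild-type) and 0.94 (empty vector against wild-type). Without a filter the counts were 1 in empty vector against wild-type and 13 against both controls, with 3 lists in empty vector against wild-type, and the filter at the 75th percentile gave 6 in empty vector against wild-type. IL2 had no value under that filter.

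Without the intensity trend the counts were 5 in IL-2 against wild-type, 5 in empty vector against wild-type and 5 against both controls. With only the 2 groups compared they were 72 in IL-2 against empty vector (111 reported) and 1 in empty vector against wild-type. The experiment number as a block gave 235, 53, 31 and 47 in IL-2 against empty vector, IL-2 against wild-type, empty vector against wild-type and against both controls. The numbers missed the cut-off of 0.1 for 1 pair in empty vector against wild-type. Yet each empty vector array correlated more with the wild-type array of its own number (0.251, 0.0940 and 0.165) than with the others (at most 0.0562). There the lymphocyte markers had an adjusted p of 0.0684 with the block, and none of the 59 named calls ended with it.

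With an estimated correlation 0, 0 and 0 lists passed, and with fry 1, 0 and 0, in IL-2 against empty vector, IL-2 against wild-type and empty vector against wild-type.

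Leaving out 1 array or 1 experiment number gave 13 to 100 probe sets in IL-2 against empty vector, 0 to 30 in IL-2 against wild-type, 0 to 12 in empty vector against wild-type and 0 to 25 against both controls. It gave 2 to 6, 4 to 9 and 1 to 8 lists. The IL2 difference was 0.031 to 0.57 (IL-2 against empty vector), 0.47 to 0.98 (IL-2 against wild-type) and 0.25 to 0.52 (empty vector against wild-type). The cell cycle list of IL-2 against wild-type ranged from an adjusted p of 0.000202 to 0.936, and its direction reversed without IL-2 experiment 1. Within each experiment number its mean was lower in the IL-2 line (-0.44, 0.02 and 0.16, against -0.15, 0.19 and 0.19). Experiment 1 read lowest in both lines, so leaving out 1 of its arrays unbalances the groups. The ribosomal genes were also lower within each number, at 0.21, -0.38 and -0.29 in the IL-2 line. They read 0.53, -0.04 and -0.19 in the empty vector line and 0.33, -0.12 and -0.04 in the wild-type line.

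Over 59 named calls and all settings, 807 values stayed past the threshold, 481 missed it in the same direction and 0 reversed. The median of all log2 differences lay within 0.023 of 0 under every scaling.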

Other observations

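For the patterns below, the tests on shuffled gene order and DNA copy number, the test on IL2, and the tests on the hypoxia and cholesterol genes were chosen after the result was seen.

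Over the 3 comparisons 20 runs of neighbouring genes were shifted together. Called genes lay in runs of their own direction more often than others did (47 of 86 against 7.37% in the IL-2 and empty vector comparison). The runs of this count were defined by uncalled genes, and a gene inside a run of the opposite direction was not counted. The strongest runs had a family-wise permutation p of 0.001, the smallest that the shuffled orders can give, which argues against a chance order of the genes for them. The largest p of a run was 0.038 in IL-2 against empty vector, 0.023 in IL-2 against wild-type and 0.001 in empty vector against wild-type. These p hold within a comparison, not over all 3. Only the gene order was shuffled, so genes that vary together between arrays were not tested. A difference with brightness was not the whole of it, since 19 runs were kept after a trend on brightness was taken off. Without the probe sets past the threshold 18 runs were kept. Runs were found by window medians, which a few strongly changed genes hardly move. The 18 was therefore nearly fixed in advance and does not test whether such genes made the runs. In the strongest run, on chromosome 11, 84.1% of the genes lay on the side of its median. A run found by its window medians holds most genes on that side anyway, so this share does not bear on a cause. A candidate explanation is DNA copy number that differs between the lines, but no DNA was measured and each construct had 1 line. Copy number therefore cannot be told apart here from other differences between the lines, and an effect of IL-2 on whole stretches was not tested.

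IL2 stayed at background on the arrays named IL-2 transgenic, with a highest intensity of 76.2. The probe sets may not read the transgene, for example if it lacks the part they target, and this cannot be told apart from low expression because the construct's sequence is not given. A wrong label was therefore not tested either. No biological explanation was tested.

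Hypoxia and cholesterol genes were lower in both transfected lines than in the wild-type line by their medians, in all 3 experiment numbers for the empty vector line but not in experiment 2 for the IL-2 line (0.10 and 0.12 higher), and the shared wild-type arrays alone bring such likeness (r = 0.306 over all probe sets against a simulated 0.501). Members that move together from array to array could account for the camera calls, since the lowest of the 4 adjusted p with an estimated correlation was 0.399. Whether a single wild-type array carries it cannot be told apart from a difference between the lines, since the median nearest 0 without 1 wild-type array was -0.16 for the hypoxia genes (SE between arrays 0.20) and -0.35 for the cholesterol genes (SE 0.31), both in IL-2 against wild-type. The cholesterol medians hung more on the transfected arrays of experiment 1, with -0.20 in IL-2 against wild-type without IL-2 experiment 1 and -0.20 in empty vector against wild-type without empty vector experiment 1. Transfection, which the design names, was not tested apart from differences between lines.

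The counts under other splits of the arrays were planned, except where a set is named as chosen later. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 111 probe sets in IL-2 against empty vector (highest other 0), 24 in IL-2 against wild-type (highest other 1) and 13 in empty vector against wild-type (highest other 0), and in each 1 of 10 splits, the real one, gave as many. For the lists 4 of 10 splits gave as many in IL-2 against empty vector (real 5, highest other 7), 1 of 10 in IL-2 against wild-type (real 8, highest other 6) and 6 of 10 in empty vector against wild-type (real 5, highest other 6). The split with 7 lists held the arrays of experiment 1 together, while one with 6 lists did not. Among the splits that part all pairs the highest other was 3 in that comparison, 4 in IL-2 against wild-type and 6 in empty vector against wild-type. For the 22 probe sets against both controls 1 of 100 groupings drawn from 840 gave as many, the real one included. This share lay under 0.05, but most of these groupings did not keep 1 array of each experiment number per group. The highest other, 14, set the 3 arrays of experiment 1 apart, which points to a structure by experiment number, and the count with that number as a block was 47. Among 100 drawn of the 108 groupings with 1 array of each number per group, a set chosen after the result was seen, the real one again was the 1 with as many, with a highest other of 20 (33 against 47 with the block). The grouping with 20 did not keep all 3 lines whole. Whether it kept the 3 IL-2 arrays together was not examined. A grouping that keeps them together could come near the real 22 for that reason alone. The 20 therefore does not tell how near groupings unlike the lines come, and chance was not excluded.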
